A study of Mus musculus with 9 samples.

How the data were processed

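Genomic DNA of Dnmt TKO mouse embryonic stem cells (J1 line, passages 7 to 10), with or without Dnmt3a2 constructs, was cut with MspI, an enzyme that cuts CCGG whether or not the cytosine of its CpG is methylated, per the labels' protocols. Fragments of 150 to 250 and 250 to 400 bp were taken from a gel, converted with bisulfite and amplified. RRBS therefore reads the CpGs near MspI sites, which lie mostly in CpG-rich DNA, and each read starts at such a site, so its first CpG belongs to the cut site. PCR copies cannot be told from separate molecules here, and intervals on reads cover counting error only.

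The submitters' processing notes name Bismark, methylKit and the build mm9, without versions or their order. The deposited tables give, per the file headers, 1 row for each CpG position and strand with its coverage (a count of reads) and the percent of reads with C and with T. Every table used holds positions covered by at least 10 reads, as checked on the values. The labels name the same table for both numbered samples of WT, of WWD, of R and of C, so the authors' counts and percent values were taken as pooled per group, an assumption the values were not used to test. If a table holds 1 of these samples only, the values are of that sample. From 6 deposited tables, 5 were used. The other is tied to no sample in the labels. In all, 8 columns of values were not used, those of that table and the percent of T in the tables used. Methylated read counts were recovered as coverage times the deposited percent of C, rounded to a whole number. Reads showing neither C nor T count as unmethylated.

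Choices were made before the data were examined unless stated otherwise. Levels are means over CpG positions covered by at least 10 reads in all 5 pools, without the mitochondrial genome, so that each group has the same positions. Their 95% intervals come from 1000 bootstrap resamples of 1 Mb blocks. CpG positions covered by at least 10 reads in both pools were compared with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment within a comparison. A position was called at an adjusted p under 0.01 and a difference of at least 25 percentage points. Tiles of 1 kb with at least 5 CpG positions in both pools were tested on summed reads and called at an adjusted p under 0.01 and a difference of at least 10 points. Summing counts a read once per CpG, so tile p-values are too small and Wilson intervals on summed reads too narrow. The fit with counts divided by the number of CpGs bounds this for the p-values. It counts a read at most once, and less in tiles wider than a read or covered on both strands. The tile difference was taken as the mean over CpGs of the percent methylated, a definition settled after the data were examined: with summed reads, 3219 of 72431 unchanged tiles were called in simulated data for WWD against WT, since reads can spread differently over a tile. WT was compared with TKO, and WWD, R and C with WT. The 5 tiles with the largest rise and the 5 with the largest fall among those called were named in each comparison, as fixed beforehand for the case without an annotation of the build. Promoter tests and gene lists were not run, since the gene table at hand belongs to another assembly and coordinates were not converted. CpG context was described by the number of covered CpG positions in the tile (under 5, 5 to 9, 10 to 19, 20 to 39, 40 or more) and by chromosome.

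Choices made after the data were examined were the depth classes, the checks on read ends, strands and chromosome depth, and the ranking of sites by R. Full-depth positions have a TKO to WT read ratio of at least 0.5. Because WT depth could itself follow WT methylation, a second class used the TKO and C tables alone. Read ends were studied on isolated autosomal fragments of 110 to 250 bp, defined as runs of positions with gaps of at most 500 bp that start on the forward and end on the reverse strand. The first CpG of an end was compared with the nearest CpG 5 to 45 bp inside it. Strand differences used CpGs at least 5 bp inside both ends of fragments of up to 100 bp. Depth was divided by the autosomal median of the same density class and summarised in 5 Mb windows with at least 100 positions. Runs of windows above 1.1 in all 5 pools were recorded, and the longest was also measured with the second class and over all positions. Because that search used all 5 pools and density-divided depth, it was repeated in WT alone, on depth not divided by density and with the second class, and the other pools were then read over the run so found.

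The tests were tried on simulated reads at the real coverage. For WWD against WT, with 1511414 CpGs, 2 of 50 CpGs changed by 25 points, 17 of 50 changed by 40 points and 0 of 1511214 unchanged CpGs were called. For R against WT, with 1690544 CpGs, 11 of 50 changed by 25 points, 34 of 50 changed by 40 points and 0 of 1690344 unchanged ones were called. Of simulated tiles changed by 15 points, 31 of 50 were called for WWD against WT, and 40 of 50 for R against WT. Of unchanged tiles, 43 of 72431 and 0 of 77081 were called in these comparisons. All simulated changes were rises in WWD or R from an intermediate level, so recovery of falls was not tried. Simulated reads were drawn independently at each CpG, at a level shared by both pools where unchanged. Reads spanning several CpGs, PCR copies and differences between libraries were left out, so these counts do not bound false calls among real tiles. Alternatives for the coverage minimum, the difference, the adjusted p, the strands, very high coverage, thinning, the tile size and the tile counts were run, and their effect is given at the end. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.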

Results

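DNA methylation was measured by reduced representation bisulfite sequencing (RRBS) in mouse J1 embryonic stem cells, a pluripotent line, that lack the DNA methyltransferases (Dnmt TKO cells), and in the same kind of cells carrying Dnmt3a2 constructs. Dnmt3a2 is the shorter isoform of the de novo DNA methyltransferase Dnmt3a. The title of the series states that a histone-recognition domain of Dnmt3a was engineered. The ADD domain of Dnmt3a, which binds the tail of histone H3, is such a domain. The 9 samples form 5 groups. TKO is 1 sample without a construct. WT (wild-type Dnmt3a2), WWD and R (mutant constructs so labelled) and C (no construct recorded in its labels) have 2 samples each. For these 4 groups the labels name 1 deposited table for both samples, and for TKO 1 table for its sample. Each table is called the pool of its group below, on the assumption that it joins the reads of both samples where there are 2; a table holding 1 of them only is not excluded. Each value below is from such a table, and no spread between replicates can be given. Each test compares the reads of 2 such pools and not conditions. Intervals are 95% bootstrap intervals over 1 Mb blocks of the genome and cover variation between sites and counting error only.

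The pools held 133814232 (TKO), 145831662 (C), 196155033 (WT), 148992409 (WWD) and 210550841 (R) read calls at CpG positions covered by at least 10 reads. Median coverage per position was 87, 66, 104, 75 and 103 reads in the same order. Together 1263118 nuclear CpG positions were covered in all 5 pools, and levels refer to these. Mitochondrial CpGs, a check on bisulfite conversion, averaged 0.125% methylated in TKO, 0.0825% in C, 0.0963% in WT, 0.129% in WWD and 0.083% in R over 152 positions. Pooled over reads, where deeply covered positions weigh most, the level was 0.598% in TKO (Wilson 95% interval 0.562 to 0.636) and 0.246% in WT (0.232 to 0.26).

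Read depth was not uniform between the pools. At 909143 of the common CpGs (72.0%) the TKO pool had at least 0.5 times as many reads as the WT pool, with medians of 133 and 136 reads. These are called full-depth positions below. At the other 353975 positions (28.0%) the median was 16 reads in TKO, 28 in WWD, 53 in C, 93 in R and 109 in WT. Methylation differed between these classes in every pool, so genome-wide mean levels are given both over all positions and at full depth. The classes were defined after the data were examined.

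**Figure D1:**
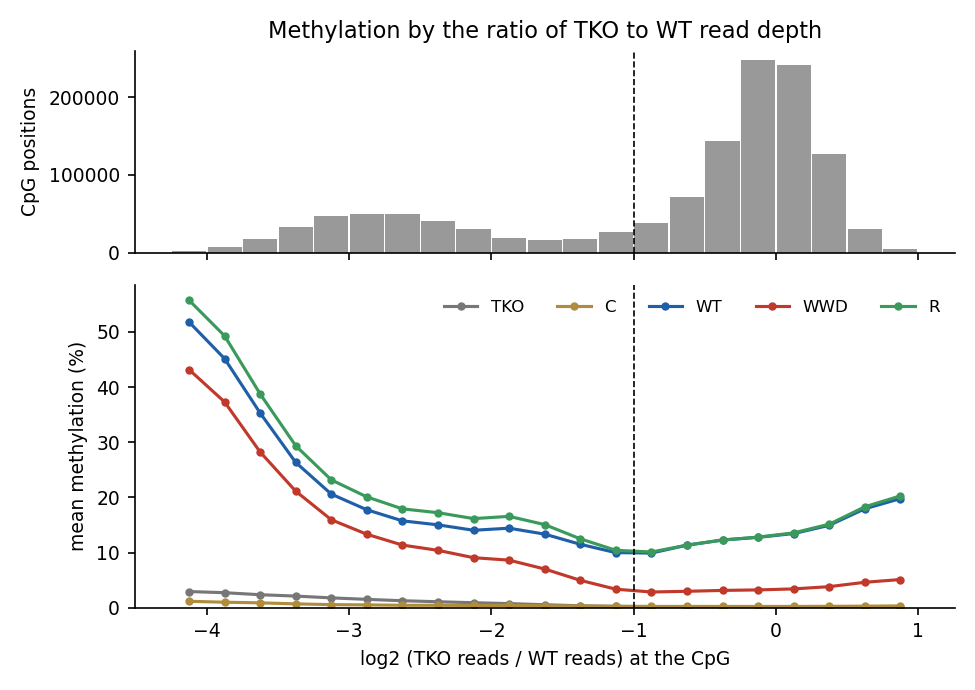
Top, number of common CpG positions by the log2 ratio of TKO to WT reads at the position; bottom, mean methylation in percent of each group in the same bins of 0.25, with the dashed line at a ratio of 0.5. All 5 curves are higher at the lowest ratios than at the line, and right of the line WT and R overlie each other, with WWD far below them.

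Cells with wild-type Dnmt3a2 were partly methylated where TKO cells were almost unmethylated, and most of the gain lay where few CpGs were covered per tile. Mean methylation was 0.501% (0.495 to 0.506) in TKO and 14.7% (14.5 to 14.98) in WT. At full-depth positions it was 0.171% (0.169 to 0.172) and 13.2% (12.9 to 13.4). Where fewer than 5 CpG positions were covered in a 1 kb tile, WT reached 28.4% at full-depth positions, against 0.246% in TKO. In tiles with 40 or more covered CpG positions WT reached 0.459%, against 0.128% in TKO. Methylation stayed incomplete: 26.4% of full-depth CpGs in WT were above 20% methylated, 7.9% were above 50% and 0.277% were above 80%.

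Of 1288864 CpG positions tested between WT and TKO, 290432 were higher and 825 lower in WT (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.01, at least 25 percentage points). Of the 825 lower positions, 824 were outside the full-depth class. Among 61366 tiles of 1 kb, 34342 were higher and 0 lower in WT, with a median rise of 33.9 points in the higher ones. The tile with the largest rise lay on chromosome 11 from 76963001 to 76964000 (mm9, as are all coordinates here). Over 6 CpG positions it held 88.3% in WT (162 read calls) and 0% in TKO (60 read calls). The upper Wilson limit in TKO was 6.02%, and the adjusted p was 1.75e-37 by Fisher's exact test. Both are too small, since a read counts once per CpG it covers. TKO had a mean of 10 reads per position in this tile, and 0% of the positions were at full depth. On chromosome 10, the tile from 111281001 to 111282000 rose from 0% (231 read calls) to 76.2% (161 read calls) over 5 positions, all at full depth. Further rises of 74.5 to 76.3 points were on chromosome 16 from 89513001 to 89514000 and on chromosome 11 from 88535001 to 88536000 and from 117770001 to 117771000. In these 5 tiles R held 56.2% to 79.3%, WWD 14.6% to 59.5% and C at most 4.31%, and the WWD value of 14.6% was that of the tile on chromosome 10. Gene annotation of this build was not used here, so no gene is named for a tile.

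**Figure D2:**
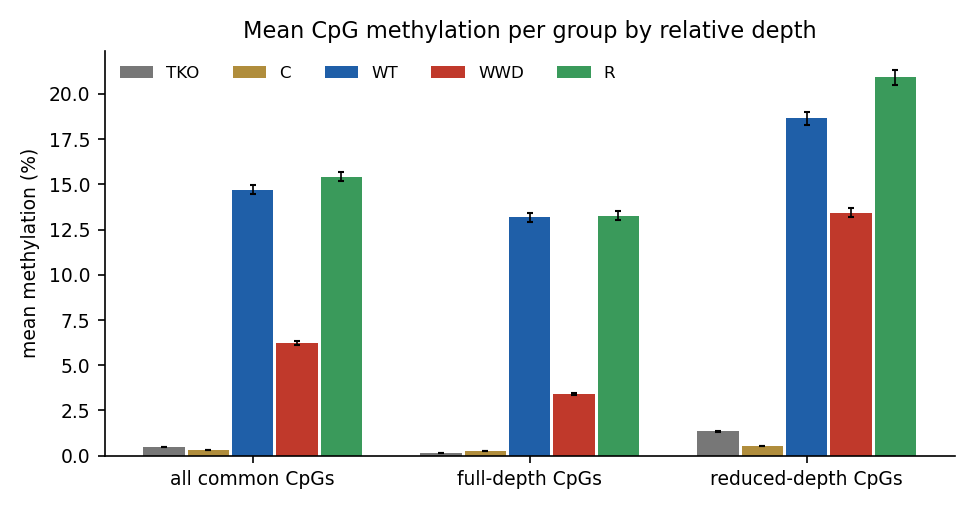
Mean CpG methylation in percent (bars) of TKO, C, WT, WWD and R over all common CpGs, full-depth CpGs and reduced-depth CpGs; whiskers are 95% block-bootstrap intervals. WWD stands at a mean of 3.39% at full depth and 13.4% at reduced depth, while WT stands at 13.2% and 18.7%.

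The WWD pool had far less methylation than the WT pool, on every autosome and on the X chromosome. The amount of construct in the cells was not measured here, so its part in the difference cannot be told from that of the mutation. WWD had a mean level of 6.20% (6.10 to 6.31) where WT had 14.7%, a ratio of 0.422 (0.42 to 0.424). At full-depth positions the level was 3.39% (3.33 to 3.45) against 13.2% in WT, a ratio of 0.257 (0.256 to 0.259). WWD had 12.4 times the TKO level over all positions and 19.9 times at full depth, where the TKO level of 0.171% was close to the 0.125% of its mitochondrial CpGs. The ratio at full depth was 0.257 on the autosomes together and 0.251 on the X chromosome. Among autosomes it was lowest on chromosome 9, at 0.25, and highest on chromosomes 3 and 19, at 0.266.

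The gain of WWD over TKO was the smallest share of the WT gain where few CpGs were covered per tile. At full-depth positions with fewer than 5 covered CpGs per tile, WWD had 6.29% and WT 28.4%. The gain of WWD over TKO there was 21.5% (21.3 to 21.6) of the WT gain. In the classes of 5 to 9, 10 to 19, 20 to 39 and 40 or more positions the share was 25.9%, 29.5%, 39.2% and 54.8% (52.5 to 57.1). Over all positions it was 37.5%, 40.003%, 44.3%, 58.6% and 105.6% (96.98 to 115.3) from the sparsest class to the densest. In the densest class the levels themselves were low, at 0.31% in WWD and 0.459% in WT. Over all positions of that class, WWD had 0.524% and WT 0.512%, and the interval of the difference reached from -0.008 to 0.03 points. The classes were not matched for place in the read, with which the WWD share also differed. At full-depth ends of isolated fragments the inner CpG had 9.35% in WWD and 31.6% in WT. The first minus the inner CpG there was -3.34 points in WWD and -1.66 in WT. How far place in the read accounts for the trend over the classes was not tested. CpGs inside full-depth reads were also ranked by their level in R, which is neither side of this comparison. WWD had 22.0% of the WT level where R had 0 to 5%, 16.2% where R had over 5 to 20%, and 19.9% where R had over 20 to 40%. The share was then 28.6% at over 40 to 60%, 44.1% at over 60 to 80% and 59.5% above 80%, where WWD had 44.8% and WT 75.3%.

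**Figure D3:**
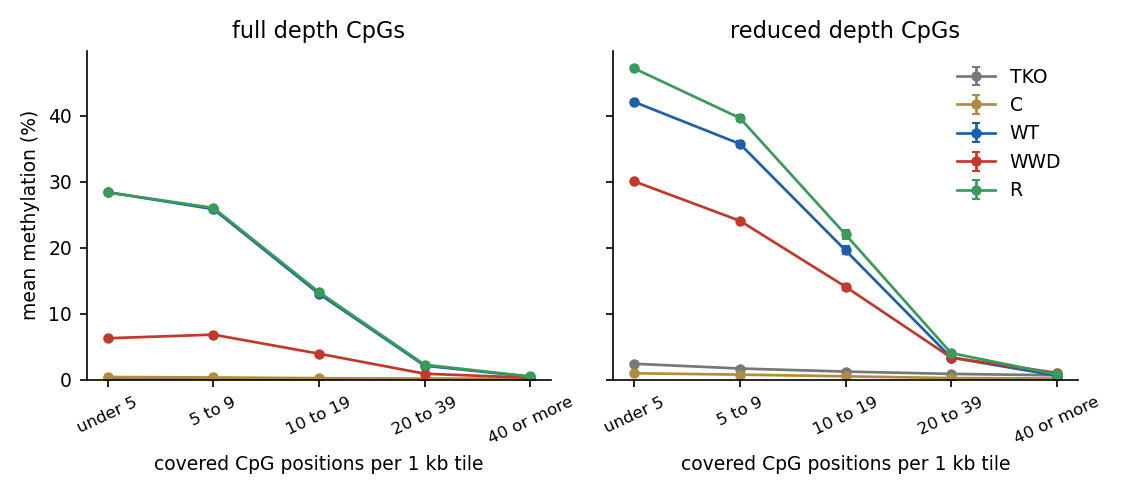
Mean methylation in percent by the number of covered CpG positions in the 1 kb tile, for full-depth CpGs (left) and reduced-depth CpGs (right), with 95% block-bootstrap intervals, most smaller than the points. WT and R fall together from 28.4% to about 0.5% on the left, where WWD starts at 6.29%; on the right WWD starts at 30.03% and R at 47.1%.

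Position by position, 202280 of 1511200 CpGs were lower and 6962 higher in WWD than in WT (Fisher's exact test, adjusted as above). At full-depth positions 159765 were lower and 6 higher. Of 72621 tiles, 35336 were lower, with a median difference of -21.6 points, and 74 were higher. The tiles called higher had 10.4% of their positions at full depth on average, against 59.9% in all tiles tested. In simulated data with no change and reads drawn independently at each CpG, 43 of 72431 tiles passed the same thresholds for this comparison. The largest fall was on chromosome 18 from 75103001 to 75104000, from 71.7% in WT (117 read calls) to 5.99% in WWD (118 read calls) over 5 CpG positions (adjusted p = 6.48e-17 by Fisher's exact test), with R at 65.05%. From summed reads the levels there were 53.0% and 5.08%. A tile on chromosome 11 from 76355001 to 76356000, with 83.3% of its positions at full depth, fell from 65.6% to 2.65%, and R held 54.4% there. Differences of -60.03 to -60.2 points were found on chromosome 5 from 76114001 to 76115000, chromosome 16 from 13660001 to 13661000 and chromosome 2 from 117045001 to 117046000. The largest rise was on chromosome 4 from 133163001 to 133164000, from 17.8% to 49.8%. Rises of 25.5 to 29.6 points were on chromosome 7 from 87173001 to 87174000, chromosome 11 from 60554001 to 60555000 and from 98823001 to 98824000, and chromosome 17 from 45885001 to 45886000. Of these 5 tiles, 4 had 0% and 1 had 20% of their positions at full depth. The rise at 98823001 was 12.3 points when taken from summed reads. In the tile of chromosome 11 that starts at 60554001 the TKO pool itself held 41.2%. The rises at that tile and at those starting at 98823001 and 45885001 no longer passed with counts divided by the number of CpGs. That division can count a read as less than once.

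The R pool had a methylation pattern close to that of the WT pool. Its mean level was 15.4% (15.2 to 15.7) over all positions. At full-depth positions it was 13.3% where WT had 13.2%, a difference of 0.0966 points (0.0725 to 0.121). The difference over all positions was 0.703 points (0.678 to 0.728), and at reduced-depth positions it was 2.26 points. Across full-depth CpGs within these pools the levels of R and WT had a Pearson correlation of 0.955, and those of WWD and WT 0.76; CpGs are not independent replicates. At full depth, R and WT held 28.4% each in the class with fewer than 5 CpGs per tile, where the difference was -0.0303 points (-0.088 to 0.026). In the class of 40 or more, R held 0.512% and WT 0.459%.

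On the X chromosome R was higher than WT. At full-depth positions R held 11.9% and WT 10.98%, a difference of 0.957 points (0.742 to 1.19), while over the autosomes together the difference was 0.0755 points (0.053 to 0.099). The X difference was 1.69 points in the class with fewer than 5 CpGs per tile, where that of the autosomes was -0.092 points, and 1.25 points in the class of 5 to 9. Among single autosomes the largest difference was 0.424 points, on chromosome 3. The Y chromosome had only 242 full-depth positions, where R held 14.97% (11.3 to 22.5) and WT 12.96% (8.1 to 21.7).

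Of 1690346 CpGs tested, 3963 were higher and 741 lower in R than in WT. At full-depth positions the split was 653 higher and 530 lower. Of 77271 tiles, 2008 were higher and 284 lower. Among the 46893 tiles with at least 0.5 of their positions at full depth, 757 were higher and 196 lower. Taking the tile counts divided by the number of CpGs left 1 tile higher and 0 lower. That division counts a read at most once, and less in tiles wider than a read or covered on both strands, so real differences can be missed. The rises among the named tiles reached from 34.1 to 44.2 points, with the top tile on chromosome 6 from 115682001 to 115683000, at 57.0% in R (94 read calls) and 12.8% in WT (77 read calls; adjusted p = 2.11e-07 by Fisher's exact test). The others were on the X chromosome from 73400001 to 73401000, chromosome 1 from 7602001 to 7603000, chromosome 18 from 37152001 to 37153000 and chromosome 10 from 97065001 to 97066000. The tile on chromosome 18 rested on uneven coverage: its levels were 42.8% and 7.02% as means over 8 CpGs, and the rise was 8.74 points when taken from summed reads. The rise of the tile on the X chromosome was 39.4 points as a mean over CpGs and 19.4 points from summed reads, with 41.5% in R and 22.1% in WT. The named falls had differences of -24.1 to -31.9 points, with the largest on chromosome 7 from 149022001 to 149023000, from 59.9% to 28.0%. One fall had all its positions at full depth, on chromosome 9 from 8774001 to 8775000, from 60% (205 read calls) to 35.5% (423 read calls). The remaining ones were on chromosome 8 from 124001001 to 124002000 and chromosome 16 from 69966001 to 69967000 and from 38513001 to 38514000. None of these 10 tiles passed with the divided counts.

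The C pool was nearly unmethylated. Its mean level was 0.334% (0.331 to 0.338), and 0.259% (0.257 to 0.262) at full-depth positions. Of 1658762 CpGs, 405037 were lower and 15 higher in C than in WT, and none of the higher ones was at full depth. Of 75323 tiles, 46481 were lower, with a median difference of -35.8 points, and 0 were higher. The 5 largest falls were on chromosome 11 from 76963001 to 76964000, chromosome 2 from 156915001 to 156916000, chromosome 18 from 69600001 to 69601000, chromosome 5 from 125435001 to 125436000 and chromosome 6 from 118704001 to 118705000. WT held 78.7% to 88.3% in them and C 0% to 1.3%. C minus TKO was -0.166 points (-0.171 to -0.161) over all positions and 0.0889 points (0.086 to 0.0918) at full-depth positions, with no test by site.

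Depth along the chromosomes was also compared, at full-depth positions and relative to autosomal positions of the same CpG density. The X chromosome had 0.492 times the autosomal depth in TKO and 0.474 times in WT. At these positions chromosome 8 had 1.21 times the autosomal depth in TKO and 1.20 times in WT, and the next highest autosome, chromosome 17, had 1.04 times in both. From 10 Mb to 95 Mb of chromosome 8, 17 consecutive windows of 5 Mb had a relative depth of 1.46 (1.39 to 1.50) in TKO, 1.46 in C, 1.48 (1.42 to 1.52) in WT, 1.46 in WWD and 1.47 in R. The rest of chromosome 8 was at 1.01 in TKO and 1.02 in WT. Over all common positions the same stretch was at 1.16 in TKO, 1.28 in C, 1.40 in WT, 1.26 in WWD and 1.34 in R. One other run of windows was above 1.1 in all 5 pools at full depth, on chromosome 17 from 20000001 to 30000000, with 2 windows at 1.26 and 1.12 in TKO. Between pools, the depth ratio of whole autosomes at full-depth positions lay within 0.984 and 1.01 in the 8 pairs of pools compared.

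**Figure D4:**
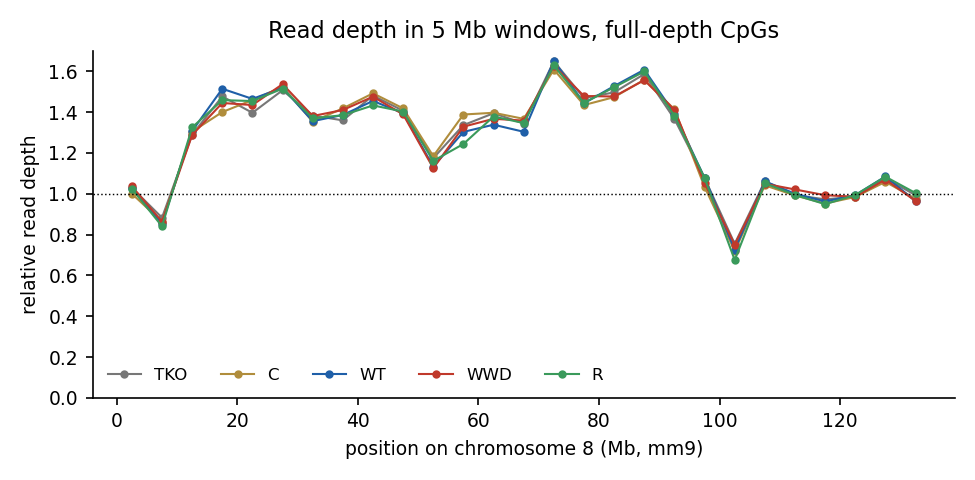
Median read depth at full-depth CpGs in 5 Mb windows of chromosome 8 (horizontal axis in Mb, mm9) relative to autosomal positions of the same CpG density, 1 line per group, with the dotted line at 1. All 5 groups lie above 1.1 from 10 Mb to 95 Mb and near 1 over most of the rest.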

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

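The filters to full-depth positions, the depth of chromosome 8 in other classes and the tile difference from summed reads were chosen after seeing the data, and the other alternatives before. Every alternative for the levels kept WT and R far above WWD and WWD above TKO and C, but C and TKO changed order between settings. The cause of each shift below was not tested here unless stated. Mean levels in the order TKO, C, WT, WWD and R were 0.259%, 0.286%, 14.0%, 4.48% and 14.3% with a coverage minimum of 20, and 0.19%, 0.266%, 13.5%, 3.77% and 13.7% with 30. They were 0.482%, 0.345%, 15.6%, 6.46% and 16.4% with strands merged, and 0.222%, 0.307%, 15.1%, 4.77% and 16.3% with reads pooled over CpGs. Full-depth positions gave 0.171%, 0.259%, 13.2%, 3.39% and 13.3%, and full depth by the TKO and C tables alone 0.179%, 0.264%, 13.7%, 3.63% and 13.8%. The 10 levels without the highest coverages or on autosomes only stayed within the intervals of the values reported.

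Called CpGs numbered 193240 for WT vs TKO, 77006 for WWD vs WT and 569 for R vs WT at 40 points, and 322619 for WWD vs WT and 10817 for R vs WT at 10 points. An adjusted p under 0.05 gave 8596 for R vs WT. With full-depth positions, fewer being tested, R vs WT had 1103 and C vs WT 202564, and with the second depth class 1181 and 195983. The other 26 CpG counts, thinned reads and merged strands included, stayed within 1.5 times the reported ones. Called tiles in the order WT vs TKO, WWD vs WT, R vs WT and C vs WT numbered 6599, 7230, 319 and 10575 with at least 10 CpG positions, 20467, 18529, 603 and 20251 with full-depth positions, and 19140, 17279, 551 and 19091 with the second depth class. Both filters leave fewer tiles to test. At 25 points, WWD vs WT had 12387 and R vs WT 31. With counts divided by the number of CpGs, R vs WT had 1. The other 17 tile counts stayed within 1.5 times.

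With a coverage minimum of 20, WWD minus WT was -21.1 points (under 5 CpGs per tile), -6.17 (10 to 19), -0.656 (20 to 39), -0.0844 (40 or more) and -9.53 (autosomes). R minus WT was then 0.521, 0.643, 0.428, 0.152 and 0.0541 from the sparsest to the densest class, and 0.338 on autosomes. With full-depth positions, WWD minus WT was -22.1, -19.0, -9.06, -1.22 and -0.15 from the sparsest class to the densest, and -9.82 on autosomes. R minus WT was then -0.0303, reversed from 1.303, in the sparsest class, and 0.186, 0.25, 0.138 and 0.0527 in the denser ones, 0.0755 on autosomes and 0.957 on the X chromosome. Of 30 named tiles, 13 failed the test in some setting, 10 of them the named tiles of R vs WT. Many could not be tested under the stricter filters, so the others did not pass every setting. Only 7 could be tested with a coverage minimum of 20, 3 with full-depth positions and 2 with the second depth class. None had the 10 CpG positions of that setting. The relative depth of the long run on chromosome 8 stayed within its intervals in all 5 groups with the second depth class, whether found in all pools or in WT alone, and over all positions it was 1.16, 1.28, 1.40, 1.26 and 1.34 in the order TKO, C, WT, WWD and R. No paired analysis was possible because the labels name 1 table for the numbered samples of each group. Promoter windows, gene lists and their alternatives were not run, for want of an annotation of this build. Depth limits the calls: with a median of 16 reads in TKO and 28 in WWD outside the full-depth class, single CpGs there show only large differences.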

Other observations

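All tests in this part were chosen after the results were seen. Methylation in these cells was strand-specific at many CpGs. In short fragments, 9361 CpGs were read on both strands away from the read starts, with mean levels of 31.8% on the forward and 31.6% on the reverse strand in WT. At 32.7% of them the strands differed by at least 25 points in WT, at 37.0% in R and at 16.5% in WWD. Across these CpGs the levels of the strands had a Pearson correlation of 0.349 in WT, 0.273 in R and 0.0565 in WWD. Of 3065 CpGs differing by at least 25 points in WT, 99.2% had a difference of the same sign in R and 97.6% in WWD, and 83.1% in R and 39.6% in WWD differed by at least 25 points in that direction. Mean levels in WWD were only 10.9% on the forward and 10.7% on the reverse strand, which leaves less room for 25 points. The strand differences of WWD and WT had a correlation of 0.808 (0.800 to 0.814).

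On autosomes, the C pool held a trace of methylation that rose with the R level of the site. At CpGs inside full-depth reads C had 0.145% (0.13 to 0.159) where R had 0 to 5%, 0.251% where R had over 20 to 40%, and 0.812% (0.679 to 0.953) where R had over 80%. TKO had 0.0632%, 0.0523% and 0.0348% at the same sites. The last class held 463 CpGs. As a percent of the WT level, C had 6.48%, 1.45%, 0.825%, 0.642%, 0.685% and 1.08% from the lowest R class to the highest. Between chromosomes the trace did not follow the WT or R level. At full-depth positions with fewer than 5 CpGs per tile, C held 0.573% on the X chromosome and 0.420% on autosomes. There WT held 19.8% and 28.7%, R 21.5% and 28.6%, and TKO 0.243% and 0.247%. C was also higher on the X chromosome in every denser class. Reads of the WT or R pool alone would leave less on the X chromosome. The source of this trace was not tested, and reads of a methylated library in the C pool are not excluded as a part of it.

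The strand differences were weighed against 3 technical explanations. Counting error would leave the differences of separate libraries unrelated, but those of WT and R had a correlation of 0.913 (0.909 to 0.917), and their root mean square in WT was 25.6 points where counting gives 6.02. A loss of reads by their first CpG is argued against by a correlation of 0.908 at 3881 CpGs with both strands at full depth. Distance from the read start accounted for 0.0265% of the variance in WT. A preference of the enzyme for the bases around a site, with no copying of marks between strands in these cells, may underlie the pattern as a hypothesis, and was not tested, since no genome sequence of this build was used here.

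Positions of reduced depth had higher methylation in all pools, by the most points in WWD, at 13.4% against 3.39% at full depth. In isolated fragments of the TKO pool, 9669 read ends had reduced depth. Their first CpG exceeded the inner CpG of the same ends by 4.06 points (3.90 to 4.22), against 0.271 points at 25167 full-depth ends. In WWD the reduced-depth values were 44.7% for the first and 15.4% for the inner CpG. At full-depth ends the first minus the inner CpG was -3.34 points in WWD, -1.66 in WT, -2.13 in R and 0.223 in C. Full-depth levels, that of WWD included, thus also depended on place in the read. Reads of a methylated library in the TKO pool are argued against by the inner level of 0.0987% (0.0807 to 0.118) in TKO. A property of whole fragments is argued against less firmly, by a correlation of 0.049 (0.038 to 0.0615) between the depth ratios of a fragment's ends. The runs taken as fragments were not checked for inner MspI sites, so their ends can belong to different fragments. TKO held 1.34% at 51 to 55 bp from an end, near the 1.38% of first CpGs and unlike 0.13% at 46 to 50 bp. A loss of reads whose first CpG is unmethylated may therefore inflate levels at reduced depth, as a hypothesis. Why it would touch some ends and pools more than others stays open. No biological explanation was tested for WWD alone; TKO, which has no construct, showed the excess at first CpGs too.

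The higher depth from 10 Mb to 95 Mb of chromosome 8 was weighed over the longest run found in WT alone, on depth not divided by density, which had the same borders. CpG density is argued against by a TKO depth of 1.46 (1.41 to 1.51) among positions of like density, at full depth by the TKO and C pools, where the mix of densities in the run alone gives 0.998, and fragment length by 1.47 among 1599 ends at full depth by the TKO and WT pools, set against ends of like length. A gain that followed a construct is argued against at full depth by the TKO and C pools, by that TKO value and a WT to TKO ratio of 1.01; at reduced-depth positions, where the ratio was 1.18, it stays open, because the TKO median of 16 reads lies close to the minimum of 10. The lowest full-depth value of the other 4 pools was 1.46, in WWD, so a candidate explanation is an extra copy of this segment in cells from which all groups came. No sample of known normal copy number was used here, a cause shared by all libraries was not tested, and over all positions TKO was at 1.16 (1.07 to 1.26) and WT at 1.40. Taken position by position, the relative WT to TKO depth in the run over all positions was 1.04 (1.02 to 1.06). Full-depth positions made up 65.6% of the run and 71.9% of positions elsewhere.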
